A study of Mus musculus with 11 samples.

How the data were processed

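RNA from mouse yolk sac at embryonic day 9.5 was measured by bulk RNA sequencing in 11 libraries: 4 control, 3 H1CKO and 4 H1H2H2. Per the labels the tissue was kept in RNAlater, RNA was taken with a tissue kit from Roche, and libraries were made with the KAPA mRNA HyperPrep kit. The labels of the H1CKO libraries differ among themselves, with floxed alleles on both chromosomes in the genotype and a knockout over a floxed allele in the description. The genotype was used. The column names call the controls wild type, while their titles give 1 floxed allele, which was used. The names of control 1 and control 2 carry the same yolk sac number and different sequencing numbers, so they may come from 1 yolk sac or a number may be mistyped; the other libraries have numbers of their own. Control 1 and control 2 were treated as separate samples. Their log2 CPM had a Pearson correlation of 0.98, among 0.977 to 0.986 for all control pairs, and both are female, which does not settle the point. The labels do not state whether libraries come from separate embryos or litters, and they give no batch. Replicate numbers are not shared between groups, so samples were not paired.

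Per the submitters' processing notes, mm10, STAR 2.5.2b, featureCounts from Subread 1.5.1 and edgeR were used, with no role, order or setting given for any of them. The deposited file gives raw read counts per gene and library, per the file headers, without normalisation. It also gives expression values that the authors deposited as log2 FPKM. The log2 fold changes per comparison were deposited by the authors. The p-value and FDR columns were also deposited as the authors computed them. Only the counts were used for the tests below, and the authors' calls were compared with those made here. The file lists 15061 genes, and a gene absent from it was not analysed here. Adult-type globin genes are absent from the file.

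Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which left 14671, and libraries were scaled with TMM factors. All 11 libraries entered 1 quasi-likelihood model with a coefficient per group, and each of the 3 contrasts was tested with p adjusted by Benjamini and Hochberg at 0.05. The common biological coefficient of variation was 0.171. The adjusted p values in the report come from this edgeR model unless a set test is named. The SE of a log2 fold change is its size over the square root of F. CPM are TMM-normalised, and means are given with the SD over libraries. A fold against a group without a count is a lower bound from 3 counts over the group, and ratios with 1 to 3 counts have a 95% interval. These intervals and floors cover counting error only.

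Read counts over genes came to 12.02 to 16.82 in units of 1e+06 per library. Rn45s took 5.61% to 11.4% of the counts, and globins 0.227% to 1.37%. In simulated data of the same size, a small share of genes was raised or lowered by 1.5, 2 and 4 times. The test recovered 30.5%, 75% and 94.8% of them in the H1CKO design and 35.2%, 76.5% and 94.9% in the H1H2H2 design. It called 0.0423% and 0.0282% of unchanged genes. Genes were drawn independently and few were changed. The rates may not carry over to H1CKO against control, where 52.6% of genes were called.

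Gene lists were written before the data were examined, as were the groups, tests and alternatives. Each of 28 lists with at least 3 tested members was tested in 3 comparisons with camera (limma 3.58.1) at a preset correlation of 0.01, with p adjusted over the 84 set tests. Of these, 32 passed; with the correlation estimated from the data, 0 passed by camera. The report gives both values for each list called. Within a list, members were also adjusted over the list alone. Named genes are Hand1 and Hand2; per comparison the 10 called genes with the highest and the 10 with the lowest fold change, among those whose libraries do not overlap between the groups and whose mean is at least 5 CPM in the higher group, gene models without a name and sex-linked genes left out; up to 4 members per list with the smallest p; and, for the direct comparison, 5 genes per direction called both there and in H1CKO against control with the smallest larger adjusted p. For H1H2H2 against control, the list examples in the report were picked from the named genes after the values were seen, as those whose call was kept by every alternative that tested them. The thresholds of 0.01 and of a 1.5-fold change were applied to counts of genes only, and Rspo2 was not tested with the 1 CPM filter or with only 2 groups. Some genes that this rule names are not reported here. Genes with a near-identical copy (at least 95% identity over 300 bases and 30% of the transcript, BLAST+ 2.17.0 on GENCODE transcripts) were passed over, which left out Myl1, Fcgr3, Cwc22, Naip5 and Eno1b. Of the tested genes, 14155 have a symbol in the GENCODE annotation, 99.9% of them at an overlapping position, and 592 (4.18%) have such a copy.

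The calls in the authors' deposited table at an FDR under 0.05 were 3727 higher and 4085 lower for H1CKO against control, 1498 and 1470 for H1H2H2 against control, and 4897 and 4729 for H1H2H2 against H1CKO. Of the calls made here, 95.2%, 97.6% and 96.7% were also in that table with the same sign.

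The alternatives were DESeq2 size factors, upper-quartile factors, no filter, a filter of 1 CPM in 4 samples, the DESeq2 1.42.0 Wald test, limma-voom with quality weights, a term for sex, globin genes left out, only the 2 groups compared, an adjusted p of 0.01, a fold of at least 1.5, an estimated correlation, fry, each library left out in turn, and the controls split 2 and 2. Leaving out control 2 and H1H2H2 9 together was chosen after the data were seen. Sex was read from Xist and Y-linked transcripts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.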

Results

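RNA from the mouse yolk sac at embryonic day 9.5 was sequenced as 11 libraries. The yolk sac is the membrane around the embryo, with an outer visceral endoderm and an inner extraembryonic mesoderm that carries the first blood and vessels. HAND1 and HAND2 are related basic helix-loop-helix transcription factors, and Hand1 is a gene of the yolk sac mesoderm. The 4 control libraries come from embryos with 1 floxed Hand1 allele over a normal allele (control 1 to 4). The 3 H1CKO libraries come from embryos with 2 floxed Hand1 alleles and a Cre recombinase under the control of T (brachyury), a gene of the primitive streak (H1CKO 5 to 7). The 4 H1H2H2 libraries come from embryos in which both Hand1 alleles carry Hand2 in place of Hand1 (H1H2H2 8 to 11). The labels name a Cre only for the H1CKO libraries, so an effect of Cre cannot be told apart from the loss of Hand1. The first principal component held 69.08% of the variance and set the 3 H1CKO libraries, at 92.3 to 103.7, apart from the other 8, at -60.7 to -7.38. By Xist and Y-linked transcripts, 3 female and 1 male library made up the control group, 3 male libraries the H1CKO group, and 3 male and 1 female library the H1H2H2 group.

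Hand1 transcripts were low in both mutant groups. Hand1 (mm10 chromosome 11, 57828713 to 57832147, counted over exons) stood at 55.6 ± 26.2 CPM (TMM-normalised; SD, n = 4) in control, from 31.1 to 91.1. It fell to 7.63 ± 2.71 CPM (SD, n = 3) in H1CKO, a log2 fold change of -2.86 (SE 0.445, adjusted p = 0.000202). In H1H2H2 it fell to 9.54 ± 4.49 CPM (SD, n = 4), a log2 fold change of -2.55 (SE 0.387, adjusted p = 0.00482). The mutant groups did not differ detectably from each other in Hand1 (log2 fold change 0.32, SE 0.436, adjusted p = 0.541). Hand2 (chromosome 8, 57320983 to 57324517; 19.6% of its exon bases overlap Hand2os1) rose in H1CKO from 41.2 ± 6.65 CPM (SD, n = 4) to 78.4 ± 11.7 CPM (SD, n = 3), a log2 fold change of 0.93 (SE 0.319, adjusted p = 0.0273). In H1H2H2 Hand2 stood at 43.6 ± 25.6 CPM (SD, n = 4), a log2 fold change against control of 0.08 (SE 0.3, adjusted p = 0.873). H1H2H2 8 alone held 81.0 CPM of Hand2, against 23.6 to 35.9 CPM in the other 3 libraries, and without it the log2 fold change was -0.42 (adjusted p = 0.0752). Hand2 was lower in H1H2H2 than in H1CKO (log2 fold change -0.85, SE 0.319, adjusted p = 0.0329). Tissue of the embryo proper in the H1CKO libraries could give part of both Hand2 differences, and this was not tested. The H1CKO call on Hand2 was lost with a term for sex (0.70, adjusted p = 0.213). The H1CKO call on Hand2 was also lost without control 1 (0.91, adjusted p = 0.0551), control 2 (0.91, adjusted p = 0.0537), control 4 (0.80, adjusted p = 0.0853), H1CKO 6 (0.94, adjusted p = 0.0583) or H1CKO 7 (0.80, adjusted p = 0.101). The direct Hand2 call was lost with a term for sex (-0.78, adjusted p = 0.0616) and with only the 2 groups fitted (-0.82, adjusted p = 0.069). It was also lost without H1CKO 6 (-0.87, adjusted p = 0.0625), H1CKO 7 (-0.72, adjusted p = 0.115), H1H2H2 9 (-0.61, adjusted p = 0.0808), H1H2H2 10 (-0.74, adjusted p = 0.0946) or H1H2H2 11 (-0.72, adjusted p = 0.098).

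**Figure D1:**
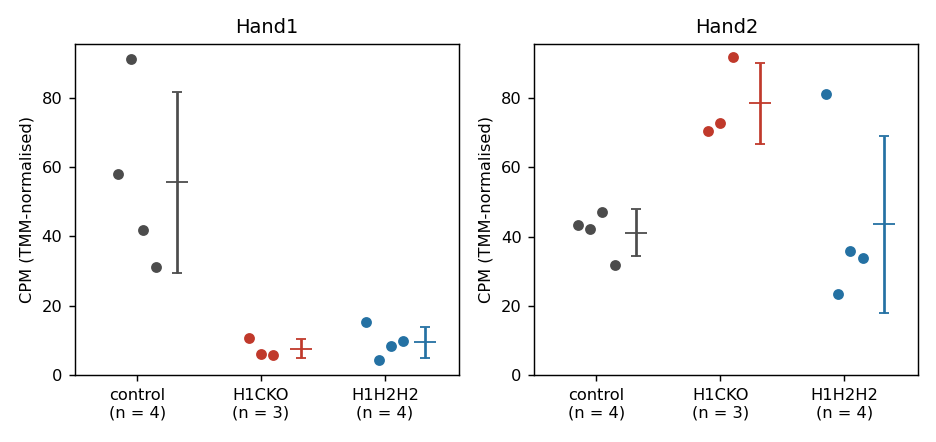
Hand1 and Hand2 in each library, in TMM-normalised CPM on linear axes from 0; points are libraries, and the bar beside each group is its mean with the SD (n = 4 control, 3 H1CKO, 4 H1H2H2). Every mutant library lies below the lowest control for Hand1 (31.1 CPM), and H1H2H2 8 (81.0 CPM) stands above the other H1H2H2 libraries for Hand2.

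The first comparison asks how the yolk sac libraries differ when Hand1 is removed by T-Cre. The H1CKO libraries held fewer transcripts of the visceral endoderm and more transcripts of the heart, neural tube and somites. Tissue of the embryo proper mixed into the H1CKO libraries could give part of the differences in this comparison, and this stays open. Visceral endoderm genes had a median log2 fold change of -1.50, and cardiac genes rose by a median log2 fold change of 5.87. Of the Notch genes 12 of 16 rose, of the Wnt genes 17 of 21 and of the hypoxia and glycolysis genes 26 of 28, and no erythroid gene was called by edgeR. With an estimated correlation none of the list calls in this comparison held (adjusted p = 0.662 for Notch, 0.689 for Wnt and 0.662 for hypoxia and glycolysis). Of 14671 genes tested, 3968 were called higher and 3753 lower in H1CKO (n = 3) than in control (n = 4), 52.6% in all, and 1892 and 1101 of them by at least 2-fold. Which direction held more calls depended on the setting. Higher and lower calls were 4512 and 3345 under upper-quartile scaling, 3713 and 4126 with no filter, 3279 and 3841 with the 1 CPM filter, 3769 and 3963 with the globins left out, and 2932 and 2964 with a term for sex. Lower calls were also more than higher ones without any 1 control, H1CKO 5 or H1CKO 6.

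Of the 26 tested visceral endoderm genes, 25 fell and 1 rose, with the same counts adjusted over the list alone. Afp, which encodes the fetal plasma protein alpha-fetoprotein (chromosome 5, 90490714 to 90508907), fell from 6332 ± 508 CPM (SD, n = 4) to 1769 ± 324 CPM (SD, n = 3; log2 fold change -1.84, SE 0.136, adjusted p = 2.49e-06). Hnf4a, a transcription factor of endoderm, changed by -1.59 (SE 0.142, adjusted p = 6.16e-06), and Lrp2, the endocytic receptor megalin, by -1.28 (SE 0.114, adjusted p = 6.14e-06). The set test called the list lower (camera adjusted p = 7.2e-11, adjusted p = 0.662 with an estimated correlation). Among the genes with the lowest fold changes, Cfi, a protease of the complement system (chromosome 3, 129836739 to 129875328), fell from 72.8 ± 8.71 to 9.57 ± 2.47 CPM (log2 fold change -2.93, SE 0.16, adjusted p = 5.67e-07). The tryptophan-degrading enzyme gene Tdo2 changed by -3.24 (SE 0.532, adjusted p = 0.000295), the drug transporter gene Abcb1a by -3.37 (SE 0.217, adjusted p = 1.2e-06), and Sgk2, Fmo2, Itih1 and Hgd by -4.23, -3.22, -2.94 and -2.88. Serpinb1a, Trim14 (38% of its exon bases overlap another gene) and Erv3 (-4.74, adjusted p = 0.0157) completed the 10 lowest. Erv3 was highest in control 2, at 43.2 CPM against 1.99 to 7.32 CPM in the other controls, and its call was not lost without that library. The Erv3 call was lost with a term for sex (-4.95, adjusted p = 0.0694) and with limma-voom (-4.91, adjusted p = 0.0598). It was also lost without H1CKO 6 (-4.27, adjusted p = 0.0601) or H1CKO 7 (-4.45, adjusted p = 0.0617).

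All 19 tested cardiac contractile genes and all 14 tested neural and somitic genes rose, with the same counts adjusted over each list alone. Myh7, a myosin heavy chain of heart muscle (chromosome 14, 54970688 to 54994549), stood at 0.33 ± 0.338 CPM (SD, n = 4) in control and 410.8 ± 220.6 CPM (SD, n = 3) in H1CKO (log2 fold change 10.23, SE 0.487, adjusted p = 3.99e-07). Myl2, a ventricular myosin light chain (chromosome 5, 122100980 to 122106854), had no count in control and was at least 1129-fold higher, taking 3 counts over the group as the floor. By the same floor, Nppa, the atrial natriuretic peptide gene, was at least 174.3-fold higher, with 61.5% of its exon bases in an overlapping gene model. The neural stem cell factor Sox2 rose from 0.385 ± 0.317 to 33.2 ± 2.21 CPM (log2 fold change 6.40, SE 0.379, adjusted p = 8.6e-07), and Meox1, of the somites, changed by 5.24 (SE 0.357, adjusted p = 1.67e-06). Otx2, a forebrain and midbrain factor with 1 count in control, gave a ratio of 638.9 (95% counting interval 114.1 to 25290). Foxb1, Pax1, Nkx6-1, Ppp1r17, Xirp1 and Foxi2 were also among the 10 highest, with Foxi2 at least 152.7-fold higher. The cardiac list was called higher (camera adjusted p = 4.98e-10, adjusted p = 0.662 with an estimated correlation). So was the neural and somitic list (median 6.27, or 6.16 with genes at 0 set to their bound, camera adjusted p = 3.52e-09, adjusted p = 0.142 with an estimated correlation). The mean log2 CPM of the cardiac list was 5.92 to 7.11 in H1CKO libraries, 0.457 to 2.02 in control and -0.0787 to 1.01 in H1H2H2.

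Signalling genes rose in the same libraries that held the cardiac and neural transcripts. Of 16 tested Notch genes, 12 rose and none fell (13 higher adjusted over the list alone, median log2 fold change 1.42, camera adjusted p = 5.14e-05, adjusted p = 0.662 with an estimated correlation). The receptor gene Notch3 rose from 32.9 ± 12.1 to 166.0 ± 14.9 CPM (log2 fold change 2.34, SE 0.236, adjusted p = 1.2e-05), and the Notch target Hey1 changed by 3.21 (SE 0.307, adjusted p = 9.04e-06). Of 21 tested Wnt genes, 17 rose and 1 fell (none without H1CKO 7), with the same counts adjusted over the list alone (median 1.51, camera adjusted p = 0.000142, adjusted p = 0.689 with an estimated correlation). Lef1, a transcription factor that acts with beta-catenin, changed by 3.89 (SE 0.448, adjusted p = 2.64e-05), and Rspo3, a Wnt agonist, by 1.99 (SE 0.22, adjusted p = 2.01e-05). In the hedgehog list 10 of 14 rose and 2 fell, and in the BMP and TGF-beta list 12 of 25 rose and 3 fell, with the same counts adjusted over each list alone. Camera called neither list (camera adjusted p = 0.0826 and 0.0657), while fry called both higher (fry adjusted p = 0.0346 and 0.00183). In the hedgehog list 6 rose and 1 fell with a term for sex. Their examples were the hedgehog ligand Shh (3.65, SE 0.587, adjusted p = 0.00026; 28.3% of its exon bases overlap another gene) and the inhibitory SMAD gene Smad6 (1.36, SE 0.133, adjusted p = 9.86e-06). Of 21 retinoid and lipid transport genes 8 rose and 9 fell (median -0.17, mean 0.68, camera adjusted p = 0.989), the same adjusted over the list alone. The retinoic acid binding protein gene Crabp2 rose by 3.02 (SE 0.254, adjusted p = 4.95e-06), and Apoc1, of lipoproteins, changed by -1.84 (SE 0.189, adjusted p = 1.33e-05).

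Of 18 tested smooth muscle genes 13 rose and none fell, the same adjusted over the list alone (median 0.94, camera adjusted p = 0.00843, adjusted p = 0.696 with an estimated correlation). Their coactivator Myocd, which heart muscle also expresses, rose from 2.32 ± 1.59 to 42.9 ± 25.8 CPM (log2 fold change 4.21, SE 0.513, adjusted p = 3.78e-05). Of 19 tested angiogenic ligand genes 14 rose and 1 fell, the same adjusted over the list alone (median 1.05, camera adjusted p = 0.00814, adjusted p = 0.662 with an estimated correlation). Vegfa rose from 84.3 ± 7.09 to 189.2 ± 31.5 CPM (log2 fold change 1.17, SE 0.101, adjusted p = 5.3e-06), and Fgf1 changed by -1.52 (SE 0.209, adjusted p = 8.72e-05). Of the angiogenic ligand genes 9 rose with a term for sex. Arterial genes rose in 8 of 14 (5 with a term for sex) and fell in 1 (10 higher and 1 lower adjusted over the list alone, median 0.83, camera adjusted p = 0.0314, adjusted p = 0.689 with an estimated correlation). Of 23 general endothelial genes 2 rose and 3 fell (2 and 2 adjusted over the list alone, median 0.19, camera adjusted p = 0.627), and of 6 venous genes 1 rose (Nr2f2, 1.42, SE 0.216, adjusted p = 0.000172; 1 adjusted over the list alone, camera adjusted p = 0.564). Extraembryonic mesoderm genes divided into 5 higher and 2 lower of 14, and mesothelial genes into 2 higher and 3 lower of 8, with the same counts adjusted over each list alone. Only 2 mesoderm genes and no mesothelial gene rose with a term for sex. Without control 3, control 4 or any 1 H1CKO library 1 mesothelial gene rose. Camera called neither the mesoderm list (median 0.49, camera adjusted p = 0.412) nor the mesothelial list (camera adjusted p = 0.725), whose median of 0.24 and mean of 0.07 were positive while the test statistic pointed lower. Fry called the mesothelial list lower (fry adjusted p = 0.0346). The mesodermal factor Twist1 rose by 1.85 (SE 0.197, adjusted p = 1.7e-05), while Postn, a secreted matrix protein gene, changed by -1.73 (SE 0.339, adjusted p = 0.00105). Matrix genes fell in 12 of 28 and rose in 3, the same adjusted over the list alone (median -0.88, camera adjusted p = 0.0479, adjusted p = 0.753 with an estimated correlation). This matrix call was lost without control 1 (adjusted p = 0.053), control 2 (-0.25, adjusted p = 0.126), control 3 (-0.95, adjusted p = 0.0649), H1CKO 5 (-0.87, adjusted p = 0.083) or H1CKO 6 (-0.89, adjusted p = 0.0842). It was also lost with DESeq2 factors, either other filter and the globins left out (adjusted p = 0.0506 to 0.0598). The proteoglycan gene Lum fell from 247.5 ± 15.6 to 40.8 ± 4.52 CPM (log2 fold change -2.60, SE 0.148, adjusted p = 7.73e-07). Adhesion genes rose in 5 of 18 (2 with a term for sex or without control 4, 3 without control 1, control 2 or H1CKO 6) and fell in 3, the same adjusted over the list alone (camera adjusted p = 0.88), with the neural and cardiac cadherin gene Cdh2 at 2.89 (SE 0.357, adjusted p = 3.98e-05).

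Of 15 primitive erythroid genes, none was called by edgeR in H1CKO, also adjusted over the list alone (camera adjusted p = 0.66; 0 at an unadjusted p under 0.05, 0 called by DESeq2 and 0 by limma-voom), and the embryonic globin gene Hbb-y stood at 1766 ± 967 CPM (SD, n = 3) against 2532 ± 1428 (SD, n = 4). The globins' share of all counts varied from 0.227% to 1.08% among the controls. Macrophage genes fell in 5 of 8 (3 with a term for sex), the same adjusted over the list alone (median -0.997, camera adjusted p = 0.0152, adjusted p = 0.496 with an estimated correlation). The mannose receptor gene Mrc1 went from 76.0 ± 12.4 to 22.8 ± 4.79 CPM (log2 fold change -1.74, SE 0.17, adjusted p = 9.95e-06). Haematopoietic progenitor genes rose in 1 of 14 and fell in 3, or in 1 without H1CKO 5 or with a term for sex (1 and 2 adjusted over the list alone, camera adjusted p = 0.412), among them the granule enzyme gene Mpo at -2.19 (SE 0.459, adjusted p = 0.00169). Inflammation and interferon genes fell in 5 of 9 and rose in 1 (5 and 2 adjusted over the list alone; camera adjusted p = 0.119, fry adjusted p = 0.000454), with the adhesion receptor gene Icam1 at -1.36 (SE 0.101, adjusted p = 2.49e-06). The rise was lost with a term for sex and without control 1, 3 or 4 or H1CKO 5 or 6. Trophoblast and decidua genes fell in 4 of 8, the same adjusted over the list alone (median -1.49, camera adjusted p = 0.0479, adjusted p = 0.689 with an estimated correlation), with the placental homeobox gene Esx1 at -2.59 (SE 0.219, adjusted p = 4.95e-06). The trophoblast set call was lost without control 1 (-1.64, adjusted p = 0.0535), control 2 (-0.44, adjusted p = 0.133), control 3 (-1.51, adjusted p = 0.0527), H1CKO 6 (-1.20, adjusted p = 0.0842) or H1CKO 7 (-1.30, adjusted p = 0.0786). It was also lost with DESeq2 factors, either other filter, the globins left out and only the 2 groups fitted (adjusted p = 0.0506 to 0.0628). Control 2 and H1CKO 5 held the most trophoblast transcripts of their groups (mean log2 CPM 4.79 and 2.98). Of 12 parietal endoderm genes 1 was lower (Thbd, adjusted p = 0.0488; none adjusted over the list alone), and the list's median of -0.05 turned positive under upper-quartile scaling. The Thbd call was lost with that scaling (adjusted p = 0.0541), with a term for sex (adjusted p = 0.209) and without control 2 (-0.85, adjusted p = 0.182), H1CKO 6 (adjusted p = 0.141) or H1CKO 7 (adjusted p = 0.151).

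Hypoxia and glycolysis genes rose in 26 of 28 and fell in 1, the same adjusted over the list alone (median 1.18, camera adjusted p = 6.47e-08, adjusted p = 0.662 with an estimated correlation). The lactate transporter gene Slc16a3 rose from 21.6 ± 3.96 to 174.4 ± 24.5 CPM (log2 fold change 3.01, SE 0.286, adjusted p = 8.75e-06). Pdk1, a pyruvate dehydrogenase kinase gene, rose by 1.44 (SE 0.124, adjusted p = 5.19e-06). Cholesterol synthesis genes divided into 2 higher and 4 lower of 20 (2 and 3 adjusted over the list alone, median 0.18, camera adjusted p = 0.819). The 2 were 7 without control 3, 1 without H1CKO 6 and none with a term for sex. The 4 were 2 without H1CKO 7. Proliferation genes (5 higher and 5 lower of 26) and p53 and apoptosis genes (5 and 5 of 19) also went both ways, the same adjusted over each list alone (camera adjusted p = 0.954 and 0.889), and in each the median (0.07 and 0.02) and the mean (-0.03 and -0.02) differed in sign. The 5 higher proliferation genes were 2 without control 1, control 2 or H1CKO 6, and 3 without control 3 or control 4 or with a term for sex. Stress response genes fell in 8 of 18 and rose in 2, the same adjusted over the list alone (camera adjusted p = 0.116, fry adjusted p = 0.00447), with the unfolded protein response factor Xbp1 at -1.29 (SE 0.135, adjusted p = 1.5e-05).

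**Figure D2:**
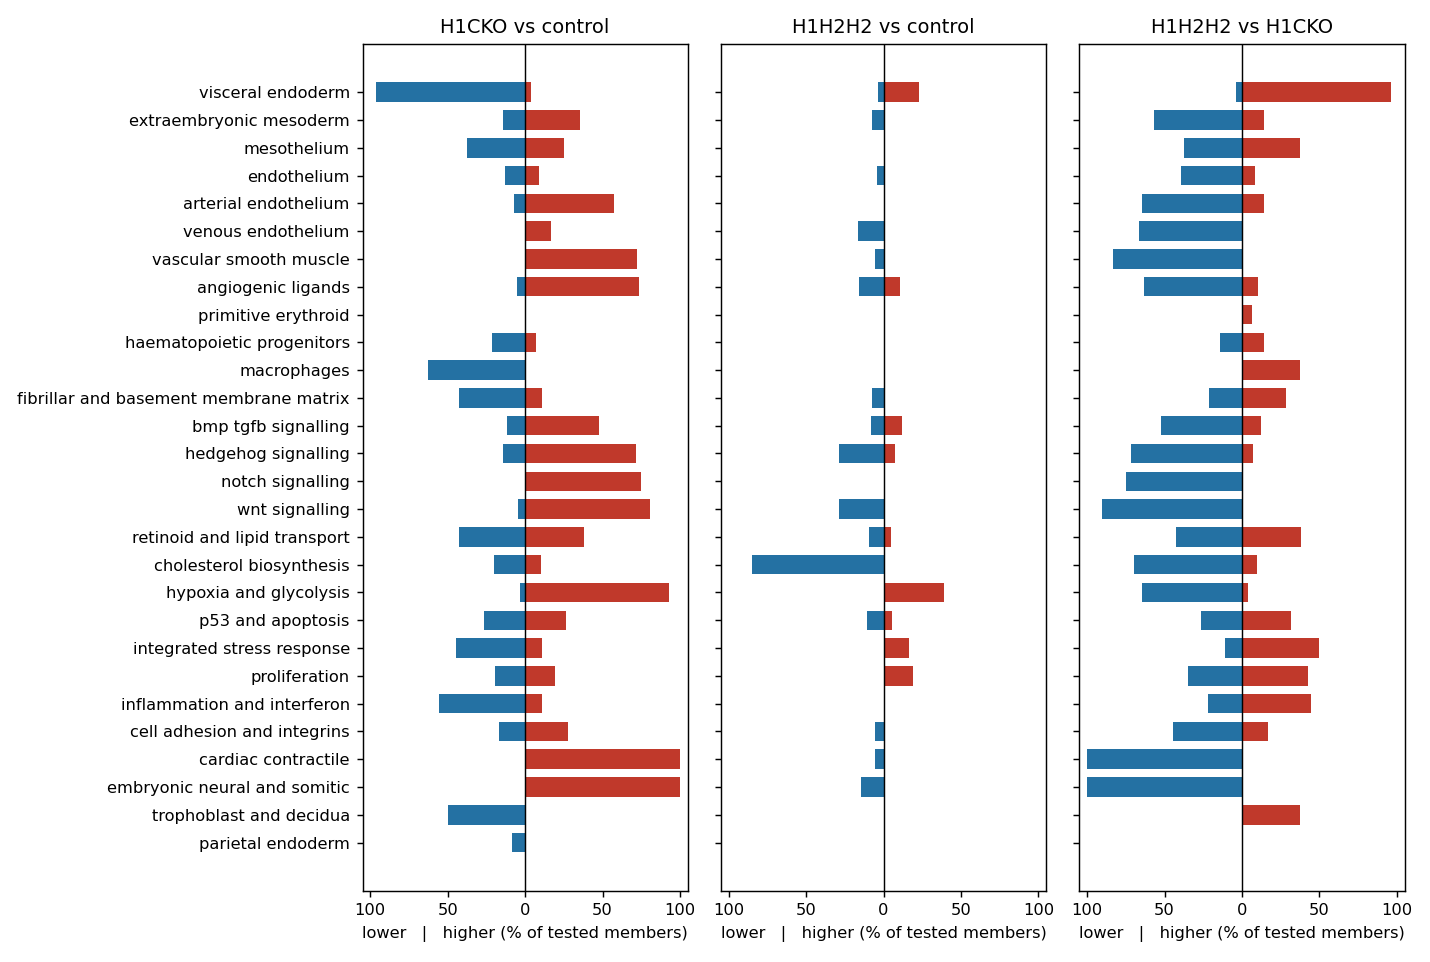
Percent of each list's tested members called higher (red, to the right) and lower (blue, to the left) at an adjusted p of 0.05, in each of the 3 comparisons. All 19 cardiac and 14 neural and somitic genes are higher in H1CKO than in control, and 17 of 20 cholesterol synthesis genes are lower in H1H2H2 than in control.

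The second comparison asks how a yolk sac with Hand2 in place of Hand1 differs from control. Of 20 tested cholesterol synthesis genes 17 fell in H1H2H2, at a median log2 fold change of -0.83, and of 28 hypoxia and glycolysis genes 11 rose. Only 1 hypoxia and glycolysis gene rose with a term for sex. Camera called both lists, and with an estimated correlation neither call held (adjusted p = 0.662 and 0.689). Of 19 cardiac genes 1 was called lower, and of 14 neural and somitic genes 2 were. None in these lists was called higher, and camera called neither list. Most visceral endoderm genes were not called. In all, 1392 genes were called higher and 1051 lower in H1H2H2 (n = 4) than in control (n = 4), 16.7% of 14671, and 103 and 287 of them by at least 2-fold. These counts rested on single libraries: without any 1 of the 8 they ran from 430 higher and 264 lower (without H1H2H2 11) to 2477 and 2578 (without H1H2H2 8). They were 461 and 347 with a term for sex, and 169 and 149 with the level of the extraembryonic mesoderm list as a term. Of the libraries, 1 of the 4 control and 3 of the 4 H1H2H2 libraries are male. With upper-quartile scaling 1083 were higher and 1330 lower, so the share of higher calls was 44.9% against 57.0%.

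The 17 cholesterol synthesis genes that fell became 19 adjusted over the list alone, and none rose (camera adjusted p = 5.8e-11, adjusted p = 0.662 with an estimated correlation). Cyp51, the lanosterol demethylase gene (chromosome 5, 4080674 to 4104697), fell from 93.3 ± 19.7 to 31.4 ± 6.21 CPM (SD, n = 4 each; log2 fold change -1.57, SE 0.174, adjusted p = 0.00069). Hmgcs1, of the mevalonate pathway (chromosome 13, 119690351 to 119708260), fell from 220.7 ± 52.4 to 88.6 ± 5.02 CPM (log2 fold change -1.32, SE 0.146, adjusted p = 0.00069). Sqle changed by -1.53 (SE 0.195, adjusted p = 0.00187) and Insig1, a sterol sensor and itself sterol-regulated, by -1.65 (SE 0.193, adjusted p = 0.000968). Lrp8, a lipoprotein receptor gene, changed by -2.03 (SE 0.24, adjusted p = 0.00109). In the retinoid and lipid transport list 1 gene of 21 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.378). With a term for sex or without control 1, control 3, H1H2H2 9 or H1H2H2 11 none rose and 1 fell. Without control 2 none rose, without H1H2H2 10 1 fell, and without H1H2H2 8 2 rose and 5 fell. The mean log2 CPM of the mesoderm list was 4.36 to 5.45 in H1H2H2 and 4.95 to 5.57 in control (exact permutation p = 0.114). H1H2H2 8 was the highest H1H2H2 library for the mesoderm list, at 5.45, while its cholesterol synthesis level of 5.28 lay under every control.

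**Figure D3:**
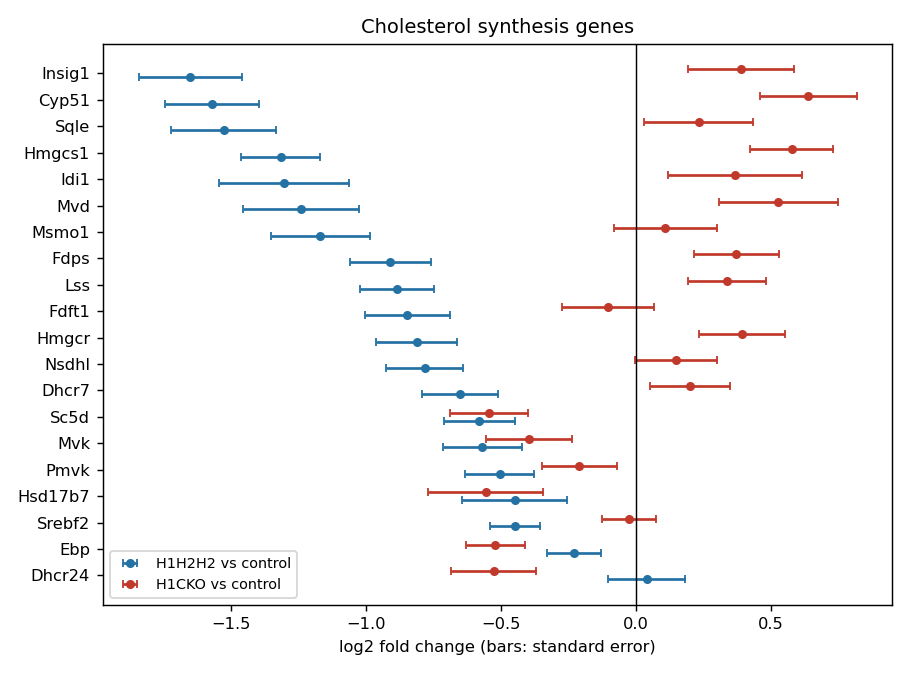
Log2 fold change of the 20 cholesterol synthesis genes in H1H2H2 (blue) and H1CKO (red), each against control, with bars for the standard error of the edgeR fit. In H1H2H2, 17 of the 20 were called lower; in H1CKO, 2 were called higher and 4 lower.

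The 11 hypoxia and glycolysis genes that rose became 13 adjusted over the list alone (median 0.43, camera adjusted p = 9.87e-05, adjusted p = 0.689 with an estimated correlation). The 11 were 4 without control 1, control 2 or H1H2H2 11, 3 without control 3, 5 without control 4 or H1H2H2 9 and 6 without H1H2H2 10. Fry did not call the list (fry adjusted p = 0.0558). The glucose transporter gene Slc2a3 rose from 2360 ± 262 to 4520 ± 1084 CPM (SD, n = 4 each; log2 fold change 0.94, SE 0.194, adjusted p = 0.0122). The list's mean log2 CPM was 6.63 in H1H2H2 9 and 5.97 to 6.12 in the other 3 H1H2H2 libraries, above the controls' 5.76 to 5.87. Wnt genes fell in 6 of 21, the same adjusted over the list alone (median -0.63, camera adjusted p = 0.000262, adjusted p = 0.689 with an estimated correlation). The 6 were 1 without control 3 or H1H2H2 11, 2 without control 1 or H1H2H2 10, 3 without control 2 or H1H2H2 9 or with a term for sex, and 10 without H1H2H2 8. The Wnt agonist gene Rspo2, without a count in H1H2H2, was at least 7.69-fold lower, from 0.39 ± 0.181 CPM in control. Hedgehog genes fell in 4 of 14 and rose in 1, the same adjusted over the list alone (median -0.46, camera adjusted p = 0.00328, adjusted p = 0.689 with an estimated correlation), with the hedgehog coreceptor gene Boc at -0.96 (SE 0.189, adjusted p = 0.0103). The 4 were 1 without H1H2H2 11 or with a term for sex and 10 without H1H2H2 8. The 1 that rose was lost with a term for sex and without any 1 library but control 4. Matrix genes fell in 2 of 28, the same adjusted over the list alone (median -0.31, camera adjusted p = 0.00743, adjusted p = 0.689 with an estimated correlation), with the proteoglycan gene Dcn at -0.90 (SE 0.19, adjusted p = 0.0131). The 2 were 1 without H1H2H2 11 or with a term for sex and 15 without H1H2H2 8. The matrix set call was lost without control 2 (-0.18, adjusted p = 0.106). Smooth muscle genes fell in 1 of 18, the same adjusted over the list alone (median -0.31, camera adjusted p = 0.0289, adjusted p = 0.752 with an estimated correlation). The 1 was none with a term for sex or without control 1, control 2, H1H2H2 9, 10 or 11, 2 without control 4 and 8 without H1H2H2 8. The smooth muscle set call was lost without control 2 (-0.17, adjusted p = 0.138), H1H2H2 9 (-0.29, adjusted p = 0.107) or H1H2H2 11 (-0.24, adjusted p = 0.0754). Venous genes fell in 1 of 6 (3 adjusted over the list alone, median -0.39, camera adjusted p = 0.0451, adjusted p = 0.689 with an estimated correlation). The venous set call was lost without control 1 (-0.34, adjusted p = 0.052), control 3 (-0.34, adjusted p = 0.0748), H1H2H2 9 (-0.30, adjusted p = 0.107), H1H2H2 10 (-0.35, adjusted p = 0.055) or H1H2H2 11 (-0.35, adjusted p = 0.0727). Extraembryonic mesoderm genes fell in 1 of 14 (none adjusted over the list alone, median -0.42, camera adjusted p = 0.0485, adjusted p = 0.752 with an estimated correlation). The mesoderm set call was lost without control 1 (-0.46, adjusted p = 0.053), control 2 (-0.36, adjusted p = 0.122), control 3 (-0.39, adjusted p = 0.12), H1H2H2 9 (-0.30, adjusted p = 0.185), H1H2H2 10 (-0.31, adjusted p = 0.0563) or H1H2H2 11 (-0.27, adjusted p = 0.0754). It was also lost with DESeq2 factors, no filter, the DESeq2 test and the globins left out (adjusted p = 0.051 to 0.0585). The 1 venous and 1 mesoderm gene were none with a term for sex or without any 1 library but H1H2H2 8, and 5 each without H1H2H2 8. The smooth muscle, venous and mesoderm set calls were also lost under upper-quartile scaling. Fry called none of the matrix, smooth muscle, venous and mesoderm lists (fry adjusted p = 0.11, 0.198, 0.0956 and 0.195).

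Visceral endoderm genes rose in 6 of 26 and fell in 1 (7 and 1 adjusted over the list alone, median 0.14, camera adjusted p = 0.0451, adjusted p = 0.806 with an estimated correlation). The 6 were 2 without control 1, 2 or 3 or H1H2H2 9 or 11, 3 without control 4 or H1H2H2 10 and 1 with a term for sex. The 1 that fell was 2 without H1H2H2 8. This set call was lost with fry (adjusted p = 0.338), a term for sex (adjusted p = 0.184), the 1 CPM filter (adjusted p = 0.0532) and without control 1 (0.12, adjusted p = 0.0535), control 2 (0.11, adjusted p = 0.148), H1H2H2 8 (0.13, adjusted p = 0.16) or H1H2H2 11 (0.10, adjusted p = 0.0695). Spink1, a trypsin inhibitor gene, rose from 65.9 ± 8.69 to 185.3 ± 68.6 CPM (log2 fold change 1.49, SE 0.283, adjusted p = 0.009), and the endoderm factor Foxa1 changed by -1.42 (SE 0.237, adjusted p = 0.00624). Cardiac genes fell in 1 of 19 and neural and somitic genes in 2 of 14, the same adjusted over each list alone (camera adjusted p = 0.0814 and 0.175). The 1 cardiac gene was none with a term for sex or without control 2, control 3, H1H2H2 9, 10 or 11, 2 without control 4 and 3 without H1H2H2 8. The 2 neural and somitic genes were 1 with a term for sex or without any 1 library but control 4 and H1H2H2 8. Proliferation genes rose in 5 of 26 and stress response genes in 3 of 18, with none lower, the same adjusted over each list alone (camera adjusted p = 0.332 and 0.0921). The 5 proliferation genes were 1 without control 1, control 3 or H1H2H2 11, 2 without control 2, H1H2H2 9 or H1H2H2 10 or with a term for sex, 3 without control 4, and 9 with 3 lower without H1H2H2 8. The 3 stress response genes were 1 without control 1, 2 or 3 or H1H2H2 9 or 11 or with a term for sex, and 5 without H1H2H2 8. Their examples were the mitotic kinase gene Cdk1 (0.43, SE 0.091, adjusted p = 0.0135) and the stress factor Atf3 (0.88, SE 0.159, adjusted p = 0.00763). BMP and TGF-beta genes divided into 3 higher and 2 lower of 25 (3 and 3 adjusted over the list alone, camera adjusted p = 0.182), with the BMP target Id1 at 0.46 (SE 0.08, adjusted p = 0.00686). The 3 were 1 without control 2 or 4 or H1H2H2 9, 10 or 11. The 2 were none without control 1 or 3 or H1H2H2 9 or 11, 1 without control 2 or 4 or H1H2H2 10, and 11 without H1H2H2 8. With a term for sex 1 rose and none fell. Angiogenic ligand genes divided into 2 higher and 3 lower of 19, the same adjusted over the list alone (camera adjusted p = 0.642), with the vascular peptide gene Apln at 1.17 (SE 0.229, adjusted p = 0.0103). The 3 were none without control 1 or 3 or H1H2H2 10 or 11, 1 without H1H2H2 9 and 6 without H1H2H2 8. p53 and apoptosis genes divided into 1 higher and 2 lower of 19 (2 and 3 adjusted over the list alone, camera adjusted p = 0.269). The 1 was none with a term for sex or without any 1 library but H1H2H2 8. The 2 were 1 with a term for sex or without control 1 or H1H2H2 11. Adhesion genes fell in 1 of 18 (Alcam, -1.14, SE 0.169, adjusted p = 0.00438; 1 adjusted over the list alone, camera adjusted p = 0.0572), and endothelial genes in 1 of 23 (none adjusted over the list alone, camera adjusted p = 0.0826). The adhesion count was 4 without control 4 and 8 without H1H2H2 8, with 1 higher without H1H2H2 9. The endothelial count was none with a term for sex or without any 1 library but control 2 and H1H2H2 8, and 7 without H1H2H2 8. In 9 lists edgeR called no member, also adjusted over each list alone, and camera called none of them: mesothelial (8 tested), arterial (14), erythroid (15), haematopoietic progenitor (14), macrophage (8), Notch (16), inflammation (9), trophoblast (8) and parietal endoderm (12). Fry called the macrophage list lower (fry adjusted p = 0.0471). At an unadjusted p under 0.05 these lists held, in the same order, 0, 1, 1, 1, 0, 3, 2, 1 and 0 members. DESeq2 called 2 Notch genes and no other member, and limma-voom called 1, 2, 2, 2, 1, 3, 2, 1 and 0. Without H1H2H2 8, 2 erythroid genes and 1 progenitor gene were higher, and 2 Notch genes and 1 mesothelial, macrophage, inflammation and trophoblast gene each were lower. Without H1H2H2 9, 2 arterial genes were higher and 1 mesothelial gene lower. Without control 3 or control 4, 1 Notch gene was lower. Parietal endoderm transcripts were uneven within groups, with a mean log2 CPM of 6.48 in control 2 and 6.33 in H1H2H2 9 against 3.98 to 4.43 in the other control and H1H2H2 libraries.

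Single genes with the highest fold changes in H1H2H2 were of mixed function. Gstm6, a glutathione transferase gene (chromosome 3, 107938848 to 107943749), rose from 0.549 ± 0.409 to 8.17 ± 1.42 CPM (SD, n = 4 each; log2 fold change 3.88, SE 0.358, adjusted p = 0.000196). Haao, which acts in tryptophan breakdown, rose from 8.49 ± 0.927 to 34.1 ± 11.0 CPM (log2 fold change 2.00, SE 0.221, adjusted p = 0.00069), and the phosphatase gene Acp1 by 1.91 (SE 0.136, adjusted p = 3.39e-05). Vwa1, Rpl22l1, Btnl5-ps, Alox12b and Bst2 rose by 1.98, 1.87, 1.71, 1.64 and 1.61. Abhd1 rose by 1.72, but 89.6% of its exon bases overlap Preb and the counts cannot be told apart. On the lower side, the membrane fusion gene Stx11 changed by -3.05 (SE 0.607, adjusted p = 0.0108), and Ctse, Col9a1, Spon1, Nr1h5, Adam22 and Padi2 by -2.60, -2.40, -2.39, -2.18, -2.02 and -1.93. With a term for sex the calls on Alox12b (1.36, adjusted p = 0.0579), Nr1h5 (-2.01, adjusted p = 0.0672), Ctse (-3.02, adjusted p = 0.111) and Padi2 (-1.84, adjusted p = 0.129) were lost. The Ctse call was also lost without control 1, 2 or 4 or H1H2H2 11 (adjusted p = 0.0533 to 0.0718), the Nr1h5 call without H1H2H2 11 (adjusted p = 0.0525), and the Padi2 call with only the 2 groups fitted and without any 1 control, H1H2H2 10 or H1H2H2 11 (adjusted p = 0.0562 to 0.109).

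The third comparison sets the replacement in H1H2H2 against the T-Cre loss in H1CKO directly. The mutant groups also differ in Cre, and Hand1 may be missing from different cells in each, which was not tested. H1H2H2 libraries held more visceral endoderm transcripts and far fewer cardiac, neural and somitic transcripts than H1CKO libraries. Tissue of the embryo proper in the H1CKO libraries stays open as a part of these differences too. Of 14671 genes, 4662 were higher and 4879 lower in H1H2H2 (n = 4) than in H1CKO (n = 3), 65% in all, and 1564 and 2540 of them by at least 2-fold. Here too the balance depended on the setting, with 3972 higher and 5639 lower under upper-quartile scaling, 4929 and 4729 with no filter, 4633 and 4238 with the 1 CPM filter, and 4782 and 4751 with the globins left out. Higher calls were also more than lower ones without H1CKO 5, H1CKO 6, H1H2H2 9, H1H2H2 10 or H1H2H2 11. Visceral endoderm genes were higher in 25 of 26 and lower in 1, the same adjusted over the list alone (median 1.64, camera adjusted p = 2.28e-09, adjusted p = 0.689 with an estimated correlation), with Afp at 8462 CPM against 1769 (log2 fold change 2.26, SE 0.139, adjusted p = 3.63e-07). All 19 cardiac genes were lower (median -6.74, camera adjusted p = 1.13e-08, adjusted p = 0.662 with an estimated correlation). All 14 neural and somitic genes were lower, the same as for the cardiac list adjusted over each list alone (median -7.65, or -6.69 with the 5 genes at 0 set to their bound, camera adjusted p = 8.18e-08, adjusted p = 0.142 with an estimated correlation). Myh7 stood at 0.0664 ± 0.077 CPM in H1H2H2 (log2 fold change -12.41, SE 0.574, adjusted p = 1.49e-07). Fsd2, Otx2, Foxb1, Sox1 and Rmst had no count in H1H2H2 and were at least 254.5-, 223.2-, 182.7-, 164.2- and 164.2-fold lower. Cfi stood at 98.4 ± 4.92 CPM (SD, n = 4; log2 fold change 3.36, SE 0.162, adjusted p = 1.49e-07), and Alox12b, Gstm6, Tmem252, Haao and Tmed6 were higher by 4.76, 4.58, 4.56, 3.91 and 3.64.

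Other lists differed directly as well. Wnt genes were lower in 19 of 21 (median -2.07, camera adjusted p = 1.63e-05, adjusted p = 0.689 with an estimated correlation). Notch genes were lower in 12 of 16 (median -1.68, camera adjusted p = 0.000199, adjusted p = 0.662 with an estimated correlation). Smooth muscle genes were lower in 15 of 18 (median -0.95, camera adjusted p = 0.00195, adjusted p = 0.689 with an estimated correlation). None of these 3 lists had a higher member (1 Wnt gene without H1H2H2 9), and the counts were the same adjusted over each list alone. Cholesterol synthesis genes were lower in 14 of 20 and higher in 2 (the same adjusted over the list alone, median -1.07, camera adjusted p = 0.00298, adjusted p = 0.752 with an estimated correlation), with Cyp51 at -2.21 (SE 0.185, adjusted p = 1.65e-06); 1 was higher without H1CKO 5 or 7. Hypoxia and glycolysis genes were lower in 18 of 28 and higher in 1 (the same adjusted over the list alone, median -0.83, camera adjusted p = 0.000895, adjusted p = 0.689 with an estimated correlation), with Slc16a3 at -2.52 (SE 0.28, adjusted p = 9.73e-06); 2 were higher without H1H2H2 8. Hedgehog genes were lower in 10 of 14 and higher in 1 (the same adjusted over the list alone, median -1.22, camera adjusted p = 0.0191, adjusted p = 0.689 with an estimated correlation). Angiogenic ligand genes were lower in 12 of 19 and higher in 2 (13 and 2 adjusted over the list alone, median -1.25, camera adjusted p = 0.0279, adjusted p = 0.689 with an estimated correlation). Stress response genes were higher in 9 of 18 and lower in 2 (the same adjusted over the list alone, median 0.38, camera adjusted p = 0.0479, adjusted p = 0.689 with an estimated correlation). This call was lost without H1CKO 5 (0.35, adjusted p = 0.0879), H1H2H2 9 (0.32, adjusted p = 0.0936) or H1H2H2 11 (0.41, adjusted p = 0.0543). It was also lost with a term for sex, DESeq2 factors, no filter, the globins left out and only the 2 groups fitted (adjusted p = 0.0506 to 0.0545). The matrix list had 8 higher and 6 lower of 28 (7 and 4 adjusted over the list alone, camera adjusted p = 0.412; 3 lower without H1CKO 7), with Lum at 2.30 (SE 0.147, adjusted p = 4.82e-07). In the erythroid list 1 of 15 was called higher (Tfrc, 1.04, SE 0.378, adjusted p = 0.029; none adjusted over the list alone), a call lost with a term for sex and without H1CKO 5 or 7 or H1H2H2 9 or 10; without H1H2H2 8, 3 were called.

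Camera called none of the lists that follow. By fry the BMP and TGF-beta, arterial, venous, mesoderm and adhesion lists were lower (fry adjusted p = 0.000323, 0.00188, 0.0203, 0.0337 and 0.0483). The macrophage, inflammation, trophoblast and retinoid lists were called as well (fry adjusted p = 0.000615, 0.00193, 0.00608 and 0.0487). Arterial genes were lower in 9 of 14 and higher in 2 (median -0.93, camera adjusted p = 0.0653). BMP and TGF-beta genes were lower in 13 of 25 and higher in 3, or 5 without H1CKO 5 (median -0.61, camera adjusted p = 0.0623). Mesoderm genes were lower in 8 of 14 and higher in 2 (median -0.99, camera adjusted p = 0.116). Venous genes were lower in 4 of 6 (camera adjusted p = 0.135), adhesion genes lower in 8 of 18 and higher in 3 (camera adjusted p = 0.412), and mesothelial genes divided into 3 and 3 of 8, with 1 lower without H1CKO 6 or H1H2H2 10 or 11 (camera adjusted p = 0.954). These 6 lists kept their counts adjusted over each list alone. Endothelial genes were lower in 9 of 23 and higher in 2 (8 and 1 adjusted over the list alone, camera adjusted p = 0.237), with 5 lower without H1CKO 6 or 7 and 1 higher without H1CKO 5 or 6 or H1H2H2 8, 10 or 11. Macrophage genes were higher in 3 of 8 (camera adjusted p = 0.121), trophoblast genes in 3 of 8 (camera adjusted p = 0.12), and inflammation genes higher in 4 of 9 and lower in 2 (camera adjusted p = 0.464). Proliferation genes divided into 11 higher and 9 lower of 26, p53 and apoptosis genes into 6 and 5 of 19 and haematopoietic progenitor genes into 2 and 2 of 14 (each camera adjusted p = 0.595). Without H1CKO 6, 5 proliferation genes were lower. Without any 1 H1CKO library or H1H2H2 11, 1 progenitor gene was lower. Retinoid and lipid transport genes divided into 8 and 9 of 21 (median 0.08, mean -0.97, camera adjusted p = 0.729). The macrophage, trophoblast, inflammation, proliferation, p53, progenitor and retinoid lists also kept their counts adjusted over each list alone. None of the 12 parietal endoderm genes was called by edgeR (camera adjusted p = 0.85; 0 at an unadjusted p under 0.05, 0 called by DESeq2 and 4 by limma-voom). Without H1CKO 5, 1 was higher and 1 lower, without H1H2H2 8 1 was higher, and without H1H2H2 9 3 were lower.

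Few genes were called in the same direction against control in both mutants. The number was 250, with 114 higher (376.5 for independent lists of these sizes) and 136 lower (268.9), and 1142 genes were called in opposite directions. Across the 14671 genes, which are not independent replicates, the log2 fold changes of the 2 comparisons had a Pearson correlation of -0.34 and a covariance of -0.22. In 20 simulations of unchanged groups against the same 4 controls, the median correlation was 0.459, the median covariance 0.0328 and the number of shared calls 0 in each. Groups without change give almost no calls, so that 0 followed from the setting and is no measure for the 250. The simulated genes were drawn independently, unlike those of real libraries. The covariance lay -0.25 from the simulated one. With the controls split 2 and 2 between the comparisons, in 6 assignments, 12 to 49 genes were called in the same direction and 44 to 556 in opposite directions, and the correlation was -0.453 to -0.212. The same-direction count was 719 without H1H2H2 8 and 73 without H1H2H2 11. Of the 3968 genes higher in H1CKO, 114 were higher, 487 lower and 3367 not called in H1H2H2 against control. Of these 3968, 3599 (90.7%) differed directly between the mutants. The cardiac gene Myh7, the long noncoding RNA gene Miat, the transcription factor gene Rfx4, Adgrv1 and Foxc2 had the strongest pairs of calls. Of the 3753 genes lower in H1CKO, 136 were lower, 655 higher and 2962 not called in H1H2H2, and 3358 (89.5%) differed directly, with Cfi, Fuca2, H6pd, Timd2 and Lum the strongest. The direct test shares the H1CKO libraries with the selection of these genes.

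**Figure D4:**
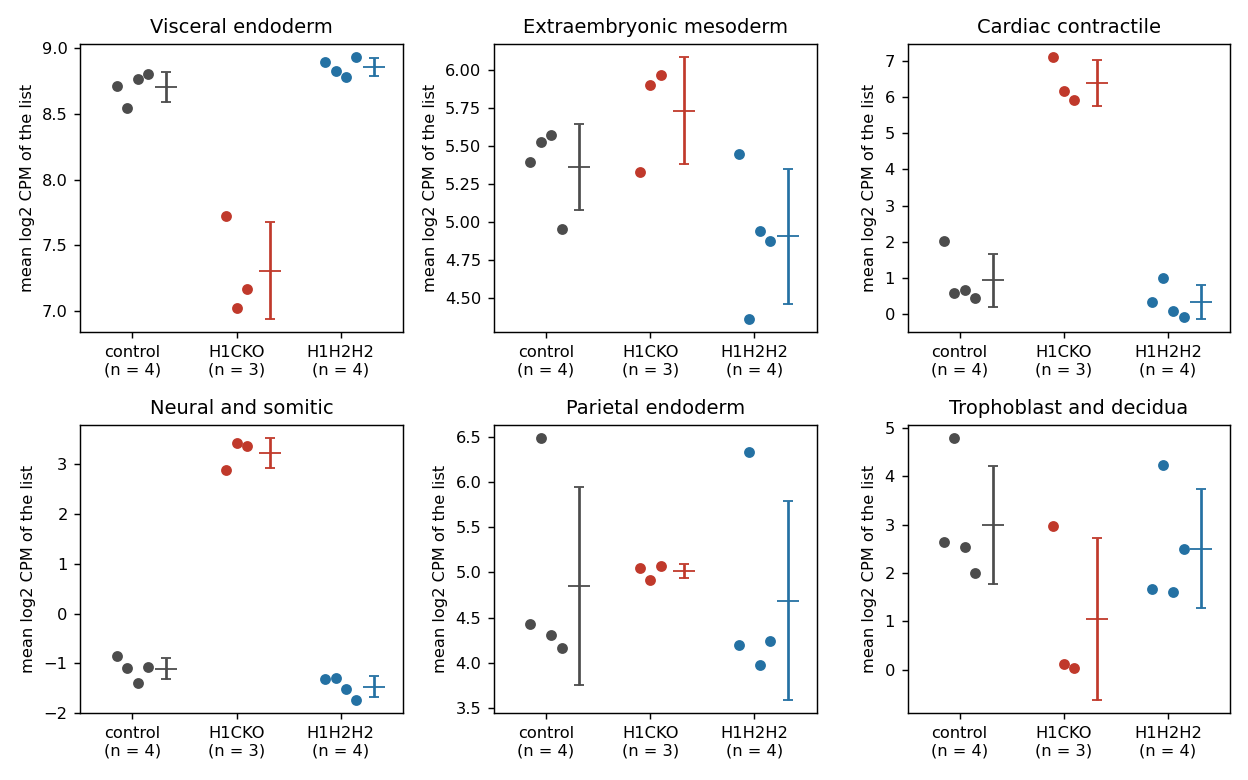
Mean log2 CPM of 6 marker lists in each library (log scale, axes not starting at 0); points are libraries, and the bar beside each group is its mean with the SD (n = 4 control, 3 H1CKO, 4 H1H2H2). Cardiac levels are 5.92 to 7.11 in H1CKO and at most 2.02 elsewhere; parietal endoderm levels are highest in control 2 (6.48) and H1H2H2 9 (6.33).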

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

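The tests on the cardiac part, on dilution, on Hand2 over the mesoderm list and on replacement transcripts were chosen after the results were seen; the other tests were written before, with untested markers added to the embryo organ and ectoderm tests later.

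In 169 groups of 4 libraries, 21 held a library far from the other 3, where 8.45 are expected by chance. Chance flags about 1 in 20 groups. Parietal endoderm lists stood high in control 2 (mean log2 CPM 6.48) and H1H2H2 9 (6.33), macrophage genes in H1H2H2 9 (2.19), matrix genes in H1H2H2 8 (8.09) and cardiac genes in control 1 (2.02), where Myh6 reached 26.8 CPM. Control 4 had the most counts of its group (15465289). Erv3 stood at 43.2 CPM in control 2 and 11.0 CPM in H1H2H2 9, Myh6 at 2.67 CPM in H1H2H2 9 and Sgk2 at 6.42 CPM in H1H2H2 8, while C5ar2 was low in control 4 (4.37 CPM). Others lie near 0: Otx2, Foxb1 and Pax1 in control 2 (0.0687 CPM each), Pax1 in H1H2H2 10 (0.0661), Nkx6-1 (0.186), Nppa and Miat (0.0622 each) in H1H2H2 9, Ppp1r17 in control 1 (0.071) and Rfx4 in H1H2H2 11 (0.275). With a group mean of at least 1 CPM asked for, a limit chosen after the values were seen, 11 of 142 groups remain.

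The H1CKO libraries hold transcripts of the heart, neural tube and somites. The 8 tested markers of ectodermal organs had a median log2 fold change of 2.58 (first quartile 2.29). The list has 16 members and a member is tested only where its transcripts are detected, so this bound could hardly be missed. With the untested members set to 0 the median is 0, but setting 8 of 16 to 0 holds it near 0 largely by construction. Neither version can decide, and genes switched on in yolk sac mesoderm stay open as the source of the ectodermal part. Tissue of the embryo proper mixed into the libraries stays open too: 77.8% of 18 tested embryo organ markers were called higher, under the 80% set beforehand, or 56% of all 25. The 19 cardiac genes cannot be told apart from a response to Hand1 loss, since no library of the embryo proper was sequenced to give a proportion. Dilution by such RNA may lower yolk sac genes; 1.79% of the 3753 lower genes fell further than the median visceral endoderm gene by over 3 SE, between the bounds set.

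Large changes of single genes in H1H2H2 had 3 explanations tested. Near-identical copies were present for 7.47% of the 375 annotated 2-fold calls (95% interval 5.02 to 10.6) and 4.09% of other genes. The share among the calls was the higher one (odds ratio 1.89, Fisher exact test p = 0.00355), so copies may play a part. It was far under the 50% needed for a main cause. Genes within 10 Mb of Hand1 made up 2.06% of the 2-fold calls (95% interval 0.892 to 4.01) and 1.34% of tested genes (Fisher exact test p = 0.256). The share of calls was under the 10% needed for linkage as a main cause. A genetic background carried in blocks could underlie part of them and stays open: 11.0% had a called neighbour, against a median of 5.13% in 10000 shuffles (permutation p = 0.0012). Strain and litter are not in the labels, and an effect of the replacement itself also stays open.

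Hand2 was not called higher in H1H2H2 than in control. Over the mesoderm list, log2 Hand2 was 0.39 higher (exact permutation p = 0.0286, the smallest that 70 arrangements can give), between the bounds of 0.25 and 0.5. The size rests on H1H2H2 8: without it the difference was 0.22, under the lower bound (p = 0.0286, exact). The direction does not, since the other H1H2H2 libraries, at 0.207 to 0.233, lay above the highest control, at 0.0533. Without a control the exact p was 0.0857 (control 1, 3 or 4) or 0.114 (control 2). The mesoderm level itself differed by -0.45 (exact permutation p = 0.114), so whether a lower share of mesoderm hides a rise stays open. Replacement transcripts not counted as Hand2 cannot be told apart from it either: 9.54 CPM of Hand1 is left, and counts per gene do not show where reads of the replaced allele were counted. H1CKO 5, 6 and 7, which have no replacement allele, stood at 0.818, 0.29 and 0.557 over the mesoderm list, also above the highest control. A higher Hand2 over this list is therefore not particular to the replacement.

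For each comparison the real split of the libraries gave more calls than any other split. The real split was 1 of 35 in each, the smallest share that so many splits can give. This speaks only to an arbitrary grouping of separate samples, not to sex, litter or another factor that follows the groups. Calls were 7721 for H1CKO against control (highest other 2555) and 2443 for H1H2H2 against control (highest other 1210). They were 9541 for H1H2H2 against H1CKO (highest other 7429). The last of these other splits groups H1H2H2 8 with the 3 H1CKO libraries. Splits that kept these 3 together with H1H2H2 10, 9 or 11 gave 3074, 833 and 3 calls. Keeping the 3 together thus does not by itself give as many.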

How the results depend on the processing

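Leaving out control 2 and H1H2H2 9 together was chosen after the data were seen; the other alternatives were chosen before. No paired analysis was possible because replicate numbers are not shared between groups. Of 264 alternatives to 15 main results, 202 stayed on the same side of the threshold or within 1.5 times the count, 56 were weaker, 6 stronger, and no called value turned its sign. Among the 202 are 4 sign changes of Hand2 in H1H2H2 against control, which was not called either way: -0.25 with limma-voom, -0.08 with a term for sex, -0.03 without control 4 and -0.42 without H1H2H2 8. For the named gene results, 5973 of 6340 were kept, 244 weaker and 123 stronger, with 12 sign changes among values not called. For 84 list results, 1398 of 1539 were kept, 93 weaker and 48 stronger, with 63 such sign changes. Every alternative chosen before ran. For H1H2H2 against control, calls higher and lower were 3053 and 2759 with limma-voom, 461 and 347 with a term for sex, 214 and 132 at an adjusted p of 0.01, 12 and 36 at a fold of at least 1.5, and 144 and 186 without control 2 and H1H2H2 9. At a fold of at least 1.5 the calls were 1744 and 1248 for H1CKO against control and 1967 and 2620 directly. Hand2 was 0.70 in H1CKO and -0.78 directly with a term for sex, -0.82 directly with only 2 groups, and -0.61 directly without control 2 and H1H2H2 9. Genes called in the same direction in both mutants were 23 at an adjusted p of 0.01 and 19 with the controls split, and in opposite directions 146 and 85. Leaving out 1 library gave 430 to 2477 higher and 264 to 2578 lower in H1H2H2 against control, 73 to 719 same-direction and 329 to 2490 opposite-direction genes, and Hand2 at 0.80 to 0.98 in H1CKO and -1.33 to -0.61 directly. The stricter thresholds call fewer genes by construction; for the other alternatives the cause was not tested.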

Other observations

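The extra lists reported here were chosen after the data were seen; the tests on cholesterol were written before. In H1CKO, anterior Hox genes were higher in 13 of 15 and none lower (median log2 fold change 2.15; Hoxa2 3.38, adjusted p = 0.000187). Complement and coagulation genes fell in 17 of 18 (median -1.47; Fga from 476.8 ± 30.1 to 128.9 ± 27.1 CPM, -1.89, adjusted p = 4.3e-06), lysosomal genes in 18 of 22 (median -0.93; Cubn -1.82) and amino acid breakdown genes in 9 of 13 with 2 higher. Fatty acid synthesis genes were higher in 8 of 13 and lower in 1, posterior Hox genes higher in 3 of 12 and lower in 1, imprinted genes higher in 4 of 24 and lower in 8, and sterol-regulated uptake genes higher in 1 of 10 and lower in 4. In H1H2H2, fatty acid synthesis genes fell in 7 of 13 and none rose: Fads2 went from 54.1 ± 9.21 to 18.4 ± 6.36 CPM (-1.56, SE 0.201, adjusted p = 0.00187), and Fads1, Scd2 and Fasn changed by -0.89, -0.64 and -0.55. Of the 10 sterol-regulated uptake genes 4 fell, Lrp8 and Insig1 among them, and Insig2 and Npc2 rose. The other lists in H1H2H2 had 4 higher of 22 (lysosome), 2 higher and 3 lower of 18 (complement), 2 higher of 13 (amino acid breakdown), 2 higher and 1 lower of 24 (imprinted), 1 lower of 15 (anterior Hox) and no edgeR call among 12 (posterior Hox).

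Cholesterol synthesis genes were lower in H1H2H2, and 2 explanations were tested. With the mesoderm list's level as a term in the model, 12 of 20 stayed lower and the median was -0.86 against -0.83, which argues against a lower share of mesoderm as the whole cause. Over all genes, 169 were called higher and 149 lower with that term, against 1392 and 1051 without it. Hand2 stood at 0.50 with the term (adjusted p = 0.147). Why the other calls were lost was not tested. Sterol-replete cells may also lower the cholesterol synthesis genes, but this stays open. The 8 tested targets of the liver X receptors had a median log2 fold change of -0.0223, which met the bound set beforehand against this explanation, but that bound was wrong: the members go both ways around it (quartiles -0.11 and 0.34), and Abcg5 (0.83, adjusted p = 0.0207) and Abcg8 (1.71, adjusted p = 0.00959) were called higher.

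Genes with near-identical copies are given apart, since reads cannot be assigned to 1 copy. Cwc22 stood at no less than 54.1 CPM in control, at most 63.6 CPM in H1CKO and 469.3 to 904.6 CPM in H1H2H2. Rpl29 stood at no less than 22.5 CPM in control, at most 24.3 CPM in H1CKO and at 197.9, 22.9, 92.8 and 92.8 CPM in H1H2H2 8 to 11. Eno1b stood at 41.2 to 55.8 CPM in control, 100 to 124 CPM in H1CKO and 0.141 to 0.808 CPM in H1H2H2. These genes were chosen after their values were seen.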
